A study of Mus musculus with 8 samples.

How the data were processed

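Total RNA from the left epididymal fat pad of 8 male mice was measured on Affymetrix GeneChip Mouse Gene 2.0 ST arrays, 1 array per mouse, from 100 ng of RNA, per the labels. The deposited values are log2 expression values from robust multiarray averaging (RMA) in Affymetrix Expression Console, per the sample descriptions and the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal by quantile normalization and summarises the probes of each probe set. Such values compress differences at low signal, and a shift common to all genes of an array is removed. Partek 6.6 is also named in the submitters' processing notes, with no role given. The annotation version and the genome build are not given in the sources used here, so no coordinates are reported. The file holds 41345 probe sets with values from 1.68 to 14.40. The labels describe the replicates as biological, and technical replicates were not made.

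Samples were grouped by the treatment in their labels, 4 mice with prednisolone and 4 with vehicle. Probe sets were named from the platform annotation table in GEO: 23521 had 1 gene symbol, 1814 had several and 16010 had none. Of the named ones, 23328 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several symbols or none were not named or tested in the main analysis. Of each gene the probe set with the highest mean over all 8 arrays was kept, giving 22180 genes, of which 1082 had more than 1 probe set. The dimmest 33.3% of genes by mean over all arrays were left out, at a log2 value of 5.82, leaving 14787 genes. Among 933 tested genes with several probe sets, 342 had differences of opposite sign between them.

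Prednisolone was compared with vehicle in limma 3.58.1 under R 4.3.3, with lmFit and eBayes at default settings on the log2 values, no covariate and no block. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The median standard error of a difference was 0.12. On simulated data with 200 changed genes among the 14787, over 10 runs, this test recovered 43.7% of genes changed 1.5-fold, 80.4% of those changed 2-fold and 93.3% of those changed 4-fold, and 4.99% of its calls were false. The simulated genes varied independently of one another, so these rates do not cover variation shared between genes.

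Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over lists with at least 5 tested members. This test compares a list with all other tested genes. In 10 simulated runs a list shifted by 0.4 was called 10 times and 0 unshifted lists were called. The simulated genes were independent, while the correlation estimated within the real lists reached 0.94 for cell cycle genes. These runs therefore do not give the rate of false calls on the real arrays. Camera with the correlation estimated per list, rank-based camera and fry were run beside it. The 33 lists covered glucocorticoid receptor targets, glucocorticoid receptors and steroid metabolism, fatty acid and cholesterol synthesis, fatty acid uptake, lipolysis, adipocyte differentiation and thermogenic genes, fatty acid oxidation, the respiratory chain, branched chain amino acid catabolism, insulin signalling, eicosanoids, extracellular matrix, inflammatory and interferon genes, MHC class II, clock, immediate early, unfolded protein response and cell cycle genes, and markers of adipose progenitors, macrophages, dendritic cells, T and NK cells, B and plasma cells, granulocytes and mast cells, endothelium, smooth muscle, mesothelium, epididymis and testis, skeletal muscle and erythroid cells. The lists, the tests, the alternatives other than those built on the epididymis score, and the rule for naming genes were fixed before the data were examined.

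The rule named the 12 largest rises and 12 largest falls past the threshold, filled up to 5 per direction from genes with unadjusted p under 0.01 and groups that do not overlap. It added the 4 members with the lowest p in each list past the list test, 1 member in each other list, and 19 fixed genes of glucocorticoid response, adipocytes and inflammation. Predicted genes, olfactory and vomeronasal receptors and small RNAs were not named. The rule gave 84 tested genes.

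A list score is the mean over tested members of each value minus its mean over the 8 arrays. Scores were compared by a two-sided exact permutation test over all assignments of 4 against 4, for which the smallest p is 0.0286. After the data were seen, the epididymis score was added as a covariate, and arrays with a score over 1 were left out, as further alternatives. The other alternatives changed the filter on dim genes, the normalization, the choice of probe set, the variance model, the array weights and the replicate block, and left out each mouse in turn. Figures were drawn with matplotlib 3.10.9.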

Results

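Gene expression was measured in the epididymal fat pad, a white adipose depot beside the epididymis, of 8 male C57BL/6 mice with 1 array per mouse. All mice ate a high-fat diet rich in n-6 fatty acids, with 45% of energy from fat, from weaning at 3 weeks of age. From 6 weeks of age, 4 mice received prednisolone, a synthetic glucocorticoid, daily in sweet potato puree for 4 weeks, and the other 4 received the puree alone as vehicle. The labels give the dose as 40 mg per kg per square metre. Fat was collected at 10 weeks of age. The comparison asks which transcripts of this depot differ with chronic glucocorticoid under this diet. Mice are named by the replicate number of their label. The deposited values are on the log2 scale, and array medians lay between 6.09 and 6.13. No arrays held identical values, and the correlation of any pair of arrays across the 14787 tested genes ranged from 0.879 to 0.986. Differences below are prednisolone minus vehicle means on the log2 scale with the standard error of the linear model (n = 4 per group). The number of arrays limits their precision.

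Transcripts of the epididymis, the duct that stores sperm and lies against this fat pad, varied more between mice than any other gene group examined, and did so in both groups. Gpx5, an epididymal glutathione peroxidase, read 13.78 in vehicle mouse 1, 13.61 in vehicle mouse 4 and 13.81 in prednisolone mouse 2, with intermediate values of 11.27 in prednisolone mouse 1 and 8.69 in vehicle mouse 3. It read 4.19 in vehicle mouse 2, 4.57 in prednisolone mouse 3 and 4.76 in prednisolone mouse 4. Adam7, an epididymal membrane protein, read 13.57, 13.21 and 13.21 in the same bright mice, 9.15 in prednisolone mouse 1 and 5.08 in prednisolone mouse 3. The epididymis and testis list score, the mean over 16 tested members of each value minus its 8-array mean, was 2.29 and 1.13 in vehicle mice 1 and 4 and 2.23 in prednisolone mouse 2. It was -2.01 and -0.73 in vehicle mice 2 and 3, and 0.22, -1.34 and -1.79 in prednisolone mice 1, 3 and 4. The group difference of the score was -0.34, with a two-sided exact permutation p of 0.8. The list did not pass the competitive gene list test (median difference -0.20, mean -0.34, adjusted p = 0.854), and 8 members were higher and 8 lower. Its median was -0.01 without vehicle mouse 1, -0.43 without vehicle mouse 2, -0.03 without prednisolone mouse 3 and 0.04 with no filter on dim genes, so its direction is not settled. Odf1, a sperm tail protein, was the member with the lowest p and read between 12.57 and 12.92 on every array (0.20 ± 0.07, adjusted p = 0.768), with a sign that turned to -0.43 when all probe sets of the gene were averaged. The first principal component of the tested genes held 59.5% of the variance. Its scores were 58.9 and 41.4 for vehicle mice 1 and 4 and 17.2 for prednisolone mouse 2, and between -15.8 and -27.0 for the other 5 mice.

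**Figure D1:**
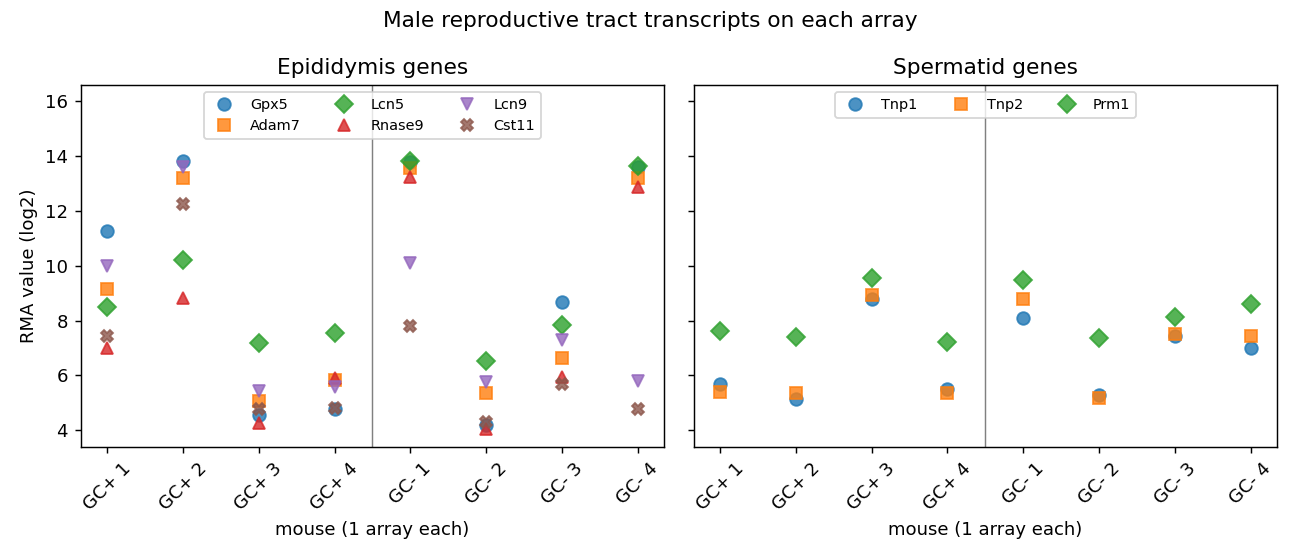
RMA values (log2, vertical axis) of 6 epididymis genes and 3 spermatid genes in each mouse (horizontal axis, GC+ for prednisolone and GC- for vehicle, 1 point per gene and array, no error bars). Gpx5 lies above 13 in prednisolone mouse 2 and vehicle mice 1 and 4, while Tnp1 is highest in prednisolone mouse 3 at 8.78.

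No gene passed the adjusted threshold, so the genes named first are the 5 largest differences in each direction among genes with an unadjusted p under 0.01 and groups that did not overlap. Differences larger than some of these, with wider errors or overlapping groups, occurred in other genes, such as Orm2 and Tat. Hspb7, a small heat shock protein of muscle, averaged 11.39 in prednisolone and 10.08 in vehicle mice, a difference of 1.31 ± 0.36. Dock8, a guanine nucleotide exchange factor of leukocytes, differed by 1.09 ± 0.20, the imprinted gene Peg10 by 1.03 ± 0.19, the metalloprotease Adam8 by 1.02 ± 0.24 and Tm4sf19, a tetraspan membrane protein, by 1.08 ± 0.24. In the other direction, 1 immunoglobulin kappa variable segment differed by -2.05 ± 0.50 and the secreted glycoprotein Stc1 by -1.51 ± 0.44. Ahcy, an enzyme of the methionine cycle, differed by -0.67 ± 0.17, the ketone body enzyme Bdh1 by -0.59 ± 0.17 and the hyaluronidase Cemip2 by -0.56 ± 0.13. Each of these 10 genes had a limma adjusted p of 0.768. Immunoglobulin segments resemble one another in sequence, so the value of that segment is uncertain. Stc1 and Bdh1 were highest in vehicle mice 1 and 4, both with high epididymis scores. Stc1 read 9.657 and 9.243 there, and Bdh1 6.618 and 6.325. The Bdh1 mean of 5.61 in prednisolone mice lay below 5.82, the cut applied to dim genes.

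With limma, 0 of 14787 tested genes passed an adjusted p of 0.05, and the lowest adjusted p was 0.71. At an unadjusted p under 0.05 there were 842 genes, 498 higher and 344 lower with prednisolone, where chance gives 739 on average. The other splits of the mice into 4 and 4 gave a median of 531.5 and up to 2838. At an unadjusted p under 0.01 there were 120 genes, where chance gives 148. The groups did not overlap in 473 genes, 3.2% of those tested, against 2.86% by chance for 4 against 4. The median difference over all tested genes was 0.018.

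Known target genes of the glucocorticoid receptor did not stand higher as a group in prednisolone mice. Of 29 tested members, 10 were higher and 19 lower, and 0 passed the adjusted threshold over all genes or adjusted over the list alone. Fkbp5, a chaperone of the receptor complex that glucocorticoids induce in many tissues, averaged 8.55 with prednisolone and 8.95 with vehicle (-0.40 ± 0.32, adjusted p = 0.791). Tsc22d3, which encodes GILZ, differed by -0.20 ± 0.18, the clock gene Per1 by -0.53 ± 0.24, and the transcription factors Zbtb16 and Klf9 by -0.16 ± 0.39 and -0.16 ± 0.20. Ddit4, an inhibitor of mTORC1 signalling, averaged 7.89 against 8.98 (-1.09 ± 0.33), and Tat, tyrosine aminotransferase, 6.12 against 7.32 (-1.20 ± 0.41). Anxa1, annexin A1, differed by 0.40 ± 0.15 and Cdkn1c, a cell cycle inhibitor, by 0.28 ± 0.10. Each of these last 4 had an adjusted p of 0.768. The list shifted down by the competitive test with a preset correlation (median -0.15, mean -0.17, adjusted p = 0.0467), and the adjusted p was 0.93 with an estimated correlation. The preset call was lost without prednisolone mouse 1 (median -0.06, adjusted p = 0.402) or 2 (-0.14, 0.164), and without vehicle mouse 2 (-0.04, 0.0517), 3 (-0.13, 0.229) or 4 (-0.04, 0.242). The median was -0.28 without vehicle mouse 1 and -0.27 without prednisolone mouse 3. It was -0.26 (adjusted p = 0.000778) with array quality weights, and the adjusted p was 0.064 without the dimmest 50% of genes. Those weights were largest for prednisolone mouse 1 (2.06) and vehicle mouse 4 (2.01). These mice had the lowest and the highest score of the list, -0.35 and 0.33, so the weighted value leans on them.

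The receptor itself, Nr3c1, averaged 9.77 in prednisolone and 9.74 in vehicle mice (0.03 ± 0.12). Hsd11b1, which regenerates active glucocorticoid inside cells, differed by 0.23 ± 0.16, and Hsd11b2, which inactivates it, by 0.25 ± 0.10. The list of glucocorticoid receptors and steroid metabolism did not pass (median 0.10, adjusted p = 0.447), and its median was 0.02 without vehicle mouse 1. Circadian clock genes did not pass either (median 0.04, mean -0.03, adjusted p = 0.925), and their median ran from -0.03 without prednisolone mouse 3 to 0.09 without prednisolone mouse 2. Arntl, the activator of the core clock, averaged 9.47 against 9.17 (0.30 ± 0.10, adjusted p = 0.768), with every prednisolone mouse above every vehicle mouse.

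**Figure D2:**
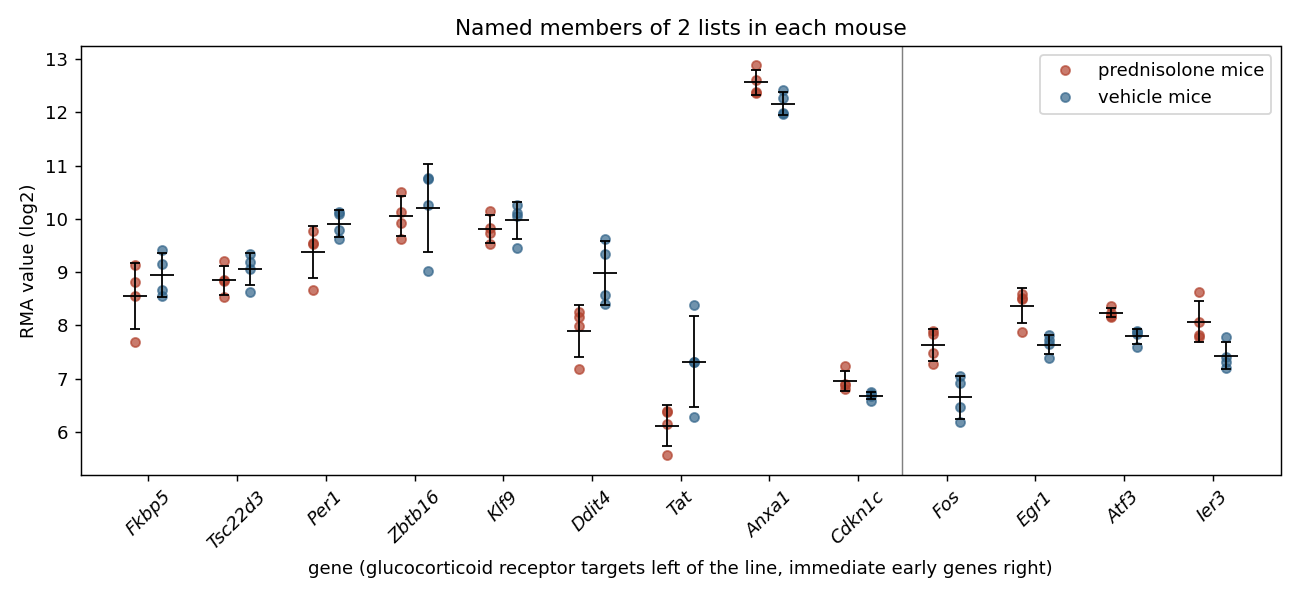
RMA values (log2, vertical axis) of 9 glucocorticoid receptor targets and 4 immediate early genes in prednisolone and vehicle mice (points are mice, horizontal bars group means, whiskers 1 SD, n = 4). Ddit4 averages 7.89 with prednisolone and 8.98 with vehicle, and Fos averages 7.63 and 6.65.

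Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were higher on average in prednisolone mice for all 17 tested members. Fos averaged 7.63 against 6.65 (0.97 ± 0.22), Egr1 8.37 against 7.64 (0.72 ± 0.17) and Atf3 8.24 against 7.80 (0.44 ± 0.09), and in these 3 genes every prednisolone mouse lay above every vehicle mouse. Ier3 differed by 0.64 ± 0.21. Over all genes the adjusted p of each was 0.768, while adjusted over the list alone 3 members passed, Atf3, Fos and Egr1, each at an adjusted p of 0.0154. The list shifted up by the preset-correlation test (median 0.23, mean 0.32, adjusted p = 1.78e-05), and the adjusted p was 0.41 with an estimated correlation. List scores ran from 0.07 to 0.25 in the 4 prednisolone mice and from -0.29 to -0.11 in the 4 vehicle mice. The two-sided exact permutation p of that score was 0.0286, the smallest that 4 against 4 can give, and 0.813 after Benjamini-Hochberg adjustment over the 32 lists.

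Macrophage markers were higher on average in prednisolone mice for 32 of 33 tested members. Mmp12, a macrophage elastase, averaged 8.92 against 7.85 (1.07 ± 0.33), Gpnmb, a glycoprotein of lipid-laden macrophages, 9.56 against 8.49 (1.07 ± 0.36), and the galectin Lgals3 8.93 against 8.30 (0.63 ± 0.21). The beta-glucan receptor Clec7a averaged 8.19 against 7.60 (0.58 ± 0.12), with the groups apart, and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0386). Cd68 and Adgre1, general macrophage markers, differed by 0.60 ± 0.37 and 0.45 ± 0.45. Over all genes 0 members passed. The list shifted up by the preset-correlation test (median 0.38, adjusted p = 5.52e-06), with an adjusted p of 0.93 with an estimated correlation and a two-sided exact permutation p of 0.143 for the score. Vehicle mice 1 and 4, both with high epididymis scores, had the lowest macrophage scores at -0.51 and -0.54, and vehicle mouse 3 at 0.39 lay within the prednisolone range of 0.05 to 0.42. Not all members followed this order. Within the vehicle group, mouse 1 was highest for Mmp12 (8.7), Gpnmb (9.03) and Clec7a (7.88), and mouse 3 lowest for Mmp12 (7.42) and Clec7a (7.4). Lgals3 went with the score, at 7.74 in vehicle mouse 4 and 8.62 in vehicle mouse 3. The list median was 0.21 without vehicle mouse 1, 0.22 without vehicle mouse 4 and 0.62 without vehicle mouse 3, and 0.61 with array quality weights. Without the 3 mice whose epididymis score exceeded 1, a choice made after seeing the data, the median was 0.02 (adjusted p = 0.178), in a fit that leaves vehicle mouse 3 as 1 of 2 vehicle mice.

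Inflammatory cytokines, chemokines and adhesion molecules were higher for 22 of 31 tested members and lower for 9. The monocyte chemoattractants Ccl2 and Ccl7 differed by 1.05 ± 0.38 and 1.07 ± 0.37, the neutrophil chemoattractant Cxcl1 by 0.40 ± 0.12, the acute phase protein Orm2 by 1.42 ± 0.52 and Tnf by 0.29 ± 0.12, each with an adjusted p of 0.768. Il6 was among the dimmest genes and was not tested; its means were 3.65 and 3.45. The list shifted up by the preset-correlation test (median 0.13, adjusted p = 0.00595), and the adjusted p was 0.93 with an estimated correlation. That call was lost without vehicle mouse 1 (median 0.05, adjusted p = 0.164) or prednisolone mouse 1 (0.12, 0.127). The median was 0.24 without vehicle mouse 2, 0.33 without vehicle mouse 3, 0.22 without prednisolone mouse 2 and 0.27 without prednisolone mouse 3. It was 0.35 (adjusted p = 0.000187) with array quality weights and 0.04 (adjusted p = 0.797) without the 3 mice of high epididymis score.

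Interferon stimulated genes were lower for 17 of 23 members. Stat2, a transducer of interferon signalling, averaged 7.83 against 8.15 (-0.32 ± 0.11), Cmpk2 differed by -0.40 ± 0.17 and Usp18 by -0.31 ± 0.19, while Ifit2 differed by 0.54 ± 0.18, each with an adjusted p of 0.768. The list shifted down with the preset correlation (median -0.12, adjusted p = 0.0467), with an adjusted p of 0.94 with an estimated correlation. The preset call was lost without vehicle mouse 2 (median -0.05, adjusted p = 0.52) or 3 (-0.08, 0.229), and without prednisolone mouse 2 (-0.10, 0.112), 3 (-0.01, 0.629) or 4 (-0.14, 0.12). The median was -0.29 without vehicle mouse 1, -0.28 without prednisolone mouse 1 and -0.34 (adjusted p = 1.15e-05) without the 3 mice of high epididymis score. It was -0.01 (adjusted p = 0.799) with array quality weights, -0.11 (0.0517) after a repeated quantile normalization and -0.22 (0.00859) without the dimmest 50% of genes.

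The other leukocyte lists did not pass. T and NK cell markers had a median of 0.03 (adjusted p = 0.447), which was 0.13 (0.0526) without prednisolone mouse 3 and -0.03 (0.82) without prednisolone mouse 1, and the interleukin 7 receptor Il7r stood at 0.73 ± 0.23. B cell and plasma cell markers had a median of 0.01 and a mean of -0.02 (adjusted p = 0.645), the median running from -0.05 without vehicle mouse 1 to 0.02 without prednisolone mouse 2, with Fcmr at -0.15 ± 0.08. Neutrophil, mast cell and eosinophil markers had a median of 0.00 and a mean of -0.06 (adjusted p = 0.358), and Kit, the mast cell growth factor receptor, averaged 7.06 against 7.42 (-0.36 ± 0.14). That list passed downward without the 3 mice of high epididymis score (median -0.19, adjusted p = 0.0133), which leaves vehicle mouse 3, with the highest score of the list at 0.39, as 1 of 2 vehicle mice. Without vehicle mouse 3 its median was 0.11, and over all 8 mice its adjusted p was 0.93 with an estimated correlation. Dendritic cell markers had a median of -0.06 (adjusted p = 0.603), which ran from -0.13 without prednisolone mouse 1 to 0.09 without prednisolone mouse 3, with Cd24a at -0.84 ± 0.66. Cd24a read at most 8.038 outside the 3 mice of high epididymis score. In those it read 10.505 and 9.942 (vehicle mice 1 and 4) and 9.438 (prednisolone mouse 2). MHC class II genes had a median of -0.01 and a mean of 0.01 (adjusted p = 0.895), with their transactivator Ciita at 0.22 ± 0.24. Without prednisolone mouse 3 the MHC class II list passed upward (median 0.27, adjusted p = 0.00591), and over the other fits without 1 mouse its median lay between -0.08 and 0.04. Over all 8 mice its adjusted p was 0.95 with an estimated correlation. Eicosanoid synthesis genes and prostanoid receptors, which act on n-6 fatty acid products, were higher for 22 of 26 members and missed the threshold (median 0.15, adjusted p = 0.0532), with the lipoxygenase Alox15 at 0.55 ± 0.26. They passed without prednisolone mouse 2 (median 0.18, adjusted p = 0.0379) or 3 (0.14, 0.0259), or vehicle mouse 3 (0.20, 0.00427). The median was 0.06 (adjusted p = 0.214) without vehicle mouse 1, 0.09 without vehicle mouse 4 or prednisolone mouse 1, and 0.02 (adjusted p = 0.35) without the 3 mice of high epididymis score. Over all 8 mice the adjusted p was 0.93 with an estimated correlation.

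Genes of lipolysis and lipid droplets were higher on average in prednisolone mice for 17 of 20 members. The lipid droplet coat protein Plin2 averaged 11.50 against 10.95 (0.55 ± 0.21), the glycerol channel Aqp7 differed by 0.34 ± 0.16, the protein kinase A subunit Prkar2b by 0.32 ± 0.14 and Plin5 by 0.20 ± 0.10. Pnpla2, the adipose triglyceride lipase, differed by 0.30 ± 0.19, with vehicle mouse 1 at 12.27 against 12.99 to 13.05 in the other vehicle mice. None passed over all genes (adjusted p = 0.768 for each of these 5), and 0 passed adjusted over the list alone. The list shifted up with the preset correlation (median 0.19, adjusted p = 0.00512), and the adjusted p was 0.93 with an estimated correlation. That call was lost without vehicle mouse 1 (median 0.12, adjusted p = 0.102), which had the lowest score of the list at -0.34 and the highest epididymis score.

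Leptin, the adipocyte satiety hormone, averaged 13.50 against 13.11 (Lep, 0.39 ± 0.13, adjusted p = 0.768). Adiponectin (Adipoq) differed by 0.13 ± 0.11 and Pparg, the main regulator of adipocyte differentiation, by 0.05 ± 0.13. The adipocyte differentiation and adipokine list did not pass (median 0.11, adjusted p = 0.0922), with an adjusted p of 0.93 with an estimated correlation. It passed without vehicle mouse 2 (median 0.18, adjusted p = 0.0276), vehicle mouse 4 (0.15, 0.0439) or prednisolone mouse 2 (0.16, 0.0314), and without vehicle mouse 1 its median was 0.00 (adjusted p = 0.74). Fatty acid uptake and triglyceride synthesis had a median of 0.10 (adjusted p = 0.159, 0.93 with an estimated correlation). Without vehicle mouse 2 the list passed (median 0.18, adjusted p = 0.0426), and over the other fits without 1 mouse its median lay between 0.07 and 0.15. Its members included the lysosomal lipase Lipa at 0.56 ± 0.19, the lipoprotein lipase Lpl at 0.03 ± 0.10 and Pck1, an enzyme of glyceroneogenesis, at -0.11 ± 0.37. De novo fatty acid synthesis had a median of 0.04 and a mean of -0.02 (adjusted p = 0.895), with the carboxylase Acacb at 0.40 ± 0.28. That median ran from -0.12 (adjusted p = 0.0587) without prednisolone mouse 3 to 0.13 (0.42) without prednisolone mouse 4. Cholesterol synthesis had a median of 0.12 (adjusted p = 0.313), with Mvd at 0.28 ± 0.15, and an adjusted p of 0.94 with an estimated correlation. It passed without vehicle mouse 1 (median 0.28, adjusted p = 0.000895), without prednisolone mouse 4 (0.23, 0.00574) and without the 3 mice of high epididymis score (0.28, 0.00847). Its median was 0.01 without vehicle mouse 3 (adjusted p = 0.854), 0.05 without prednisolone mouse 2 (0.757) and -0.01 without prednisolone mouse 3 (0.939).

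Insulin signalling and glucose use had a median of 0.01 (adjusted p = 0.895), which ran from -0.05 without prednisolone mouse 3 to 0.05 without vehicle mouse 4, and the adipocyte insulin receptor substrate Irs3 averaged 8.83 against 8.08 (0.75 ± 0.24, adjusted p = 0.768). Fatty acid oxidation had a median of 0.10 (adjusted p = 0.0548, 0.93 with an estimated correlation). It passed without vehicle mouse 4 (median 0.12, adjusted p = 0.0109) or prednisolone mouse 2 (0.15, 0.0274), and its median was 0.05 (adjusted p = 0.379) without vehicle mouse 1. The mitochondrial respiratory chain had a median of 0.01 and a mean of 0.00 (adjusted p = 0.603), the median running from -0.03 without vehicle mouse 3 to 0.04 without prednisolone mouse 2, with Cox4i1 at -0.13 ± 0.08. Branched chain amino acid catabolism had a median of 0.04 (adjusted p = 0.808), with Hibch at 0.28 ± 0.11, and the median ran from -0.02 (0.674) without vehicle mouse 3 to 0.10 (0.0507) without vehicle mouse 4. Thermogenic adipocyte genes had a median of 0.01 (adjusted p = 0.313), or 0.12 without vehicle mouse 2, with the creatine transporter Slc6a8 at 0.33 ± 0.13. Ucp1, the uncoupling protein of brown fat, was among the dimmest genes and was not tested; its means were 6.04 and 5.41, and without the filter on dim genes the adjusted p was 0.79.

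Extracellular matrix and fibrosis genes were higher for 26 of 33 members. The matricellular protein Thbs1 averaged 11.48 against 10.12 (1.36 ± 0.50), the collagen cross-linking enzyme Lox differed by 0.70 ± 0.34, Col4a2 by 0.37 ± 0.22 and Tnc by 0.29 ± 0.14, each with an adjusted p of 0.768. Thbs1 read 8.60 in vehicle mouse 1 against 10.46 to 10.80 in the other vehicle mice. The list shifted up with the preset correlation (median 0.21, adjusted p = 0.0292), and the adjusted p was 0.93 with an estimated correlation. The call was lost without vehicle mouse 1 (median 0.10, adjusted p = 0.215) or 4 (0.05, 0.483), and without prednisolone mouse 1 (0.16, 0.127) or 4 (0.15, 0.0563). Without the 3 mice of high epididymis score the median was -0.09 (adjusted p = 0.358).

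Unfolded protein response genes were lower for 18 of 21 members. The endoplasmic reticulum chaperones Canx, Hsp90b1 and Calr differed by -0.33 ± 0.15, -0.26 ± 0.16 and -0.27 ± 0.17, and Herpud1 by -0.23 ± 0.14, each with an adjusted p of 0.768. The list shifted down with the preset correlation (median -0.22, adjusted p = 0.00512), with an adjusted p of 0.93 with an estimated correlation. Its score was highest in the mice with high epididymis scores, at 0.44 and 0.21 in vehicle mice 1 and 4 and 0.07 in prednisolone mouse 2, and lay between -0.11 and -0.19 in the other 5 mice. Without vehicle mouse 1 the median was -0.07 (adjusted p = 0.272), and without those 3 mice it was 0.02 (adjusted p = 0.872).

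Cell cycle genes were lower for 23 of 26 members, and vehicle mouse 3 decided this. The replication helicase subunit Mcm4 differed by -0.29 ± 0.23, the ribonucleotide reductase subunit Rrm2 by -0.28 ± 0.31, and the kinetochore proteins Cenpe and Cenpf by -0.38 ± 0.42 and -0.33 ± 0.38. The list shifted down with the preset correlation (median -0.25, adjusted p = 0.0407), with an adjusted p of 0.94 with an estimated correlation. Without vehicle mouse 3 it shifted up (median 0.28, adjusted p = 1.75e-05), and without prednisolone mouse 3 (-0.22, 0.0752) or 4 (-0.19, 0.142) the call was lost. With array quality weights the median was 0.11 (adjusted p = 0.891), and without the dimmest 50% of genes the adjusted p was 0.0815. The median was -0.38 without vehicle mouse 1, -0.46 without vehicle mouse 4 and -0.79 (adjusted p = 2.24e-10) without the 3 mice of high epididymis score, a fit in which vehicle mouse 3 is 1 of 2 vehicle mice.

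Among markers of other cell types, endothelial genes were lower for 15 of 18 members and missed the threshold (median -0.18, adjusted p = 0.056), with Emcn at -0.27 ± 0.21. They passed without vehicle mouse 1 (median -0.38, adjusted p = 4.36e-06), without prednisolone mouse 4 (-0.32, 4.56e-06) and without the 3 mice of high epididymis score (-0.35, 1.2e-05). The median was -0.05 without prednisolone mouse 3 (adjusted p = 0.719), -0.07 without vehicle mouse 2 (0.614), and -0.10 without vehicle mouse 3 (0.327) or prednisolone mouse 2 (0.284). Over all 8 mice the adjusted p was 0.94 with an estimated correlation. Adipose progenitor and fibroblast markers had a median of 0.13 (adjusted p = 0.313), with Cd55 at 0.56 ± 0.24, and an adjusted p of 0.94 with an estimated correlation. They passed without vehicle mouse 3 (median 0.26, adjusted p = 0.0194) or prednisolone mouse 3 (0.21, 0.0367), and had a median of 0.03 without vehicle mouse 1 (adjusted p = 0.931) and 0.04 without prednisolone mouse 1 (0.79). Smooth muscle and pericyte markers had a median of -0.17 and a mean of 0.01 (adjusted p = 0.383), with Synpo2 at 0.63 ± 0.22, and passed downward without the 3 mice of high epididymis score (median -0.23, adjusted p = 0.0487). Over all 8 mice their adjusted p was 0.93 with an estimated correlation. Mesothelial markers had a median of 0.02 and a mean of -0.02 (adjusted p = 0.74), with Krt19 at -0.49 ± 0.30, and an adjusted p of 0.95 with an estimated correlation. They passed downward without vehicle mouse 4 (median -0.29, adjusted p = 0.0389) and without the 3 mice of high epididymis score (-0.37, 0.0133), while the median was 0.39 (adjusted p = 0.171) without vehicle mouse 3. Skeletal muscle markers had a median of 0.08 (adjusted p = 0.21), which ran from 0.03 without prednisolone mouse 3 to 0.13 without prednisolone mouse 2, and the skeletal actin Acta1 averaged 8.74 against 7.75 (0.99 ± 0.39). Acta1 read 9.975 in prednisolone mouse 4 and between 8.061 and 8.748 in the other prednisolone mice. Of the erythroid markers only Slc4a1 was bright enough to test (-0.09 ± 0.17), so that list had no test.

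**Figure D3:**
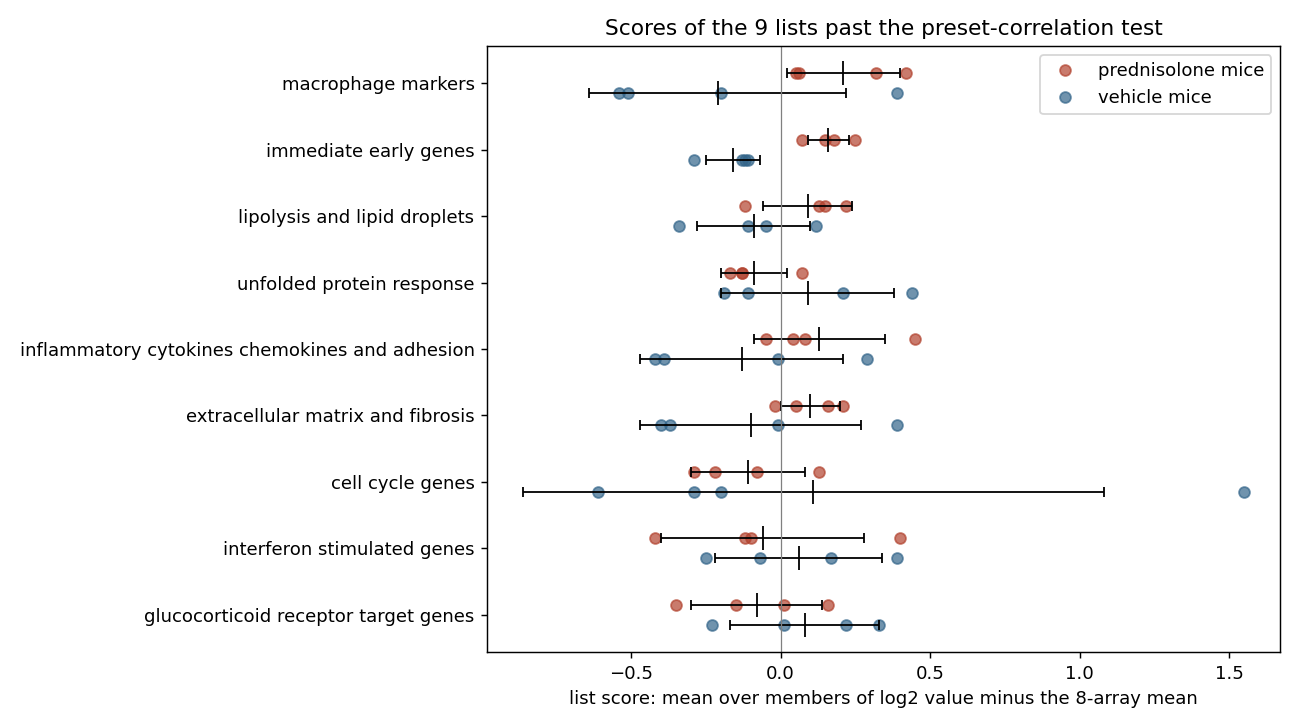
List scores (horizontal axis, mean over tested members of the log2 value minus its 8-array mean) of the 9 lists past the preset-correlation test (vertical axis), by group (points are mice, ticks group means, whiskers 1 SD, n = 4). The groups separate for immediate early genes, with prednisolone mice at 0.07 or above and vehicle mice at -0.11 or below, and overlap for the other 8 lists.

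In all, 9 of 32 tested lists passed the preset-correlation test, 5 upward and 4 downward. With the correlation estimated in each list 0 passed, the lowest adjusted p being 0.41 for the immediate early genes. With the epididymis score as a covariate, also chosen after seeing the data, the adjusted p was 0.0541 for glucocorticoid receptor targets, 0.0541 for interferon stimulated genes, 0.0537 for cell cycle genes and 0.00609 for endothelial markers, and the other 6 of the 9 lists passed. The 3 mice left out elsewhere were those with a score over 1, so prednisolone mouse 1, at 0.22, stayed in those fits. Fry, which asks whether the members of a list move on balance in one direction, gave 0 lists and a lowest adjusted p of 0.18. Adjusted over the list alone, members passed in 2 lists, 3 immediate early genes and 1 macrophage marker, and 0 in every other tested list, while over all genes 0 passed in any. Adjustment over a list alone does not correct across the 32 lists, so chance can give passing members in a few of them.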

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

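In 232 groups of 4 mice, for the score of each tested list and the value of each named gene, 17 had 1 mouse far from the other 3. Chance gives about 12, since it marks about 1 in 20 groups.

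Among list scores, MHC class II genes stood at -0.74 in prednisolone mouse 3, against 0.19 to 0.35 in the other prednisolone mice, and at 0.21 in vehicle mouse 2, against -0.10 to -0.06 in the other vehicle mice. Insulin signalling and glucose use stood at -0.12 in prednisolone mouse 2, against 0.05 to 0.07. Immediate early genes stood at -0.29 in vehicle mouse 1, against -0.13 to -0.11. The unfolded protein response stood at 0.07 in prednisolone mouse 2, against -0.17 to -0.13.

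Vehicle mouse 1 stood apart in 3 named genes, with Thbs1 at 8.60 against 10.46 to 10.80 in the other vehicle mice, Nr3c1 at 9.43 against 9.81 to 9.89 and Pnpla2 at 12.27 against 12.99 to 13.05. Vehicle mouse 3 stood apart in 3 cell cycle genes, with Mcm4 at 8.34 against 7.39 to 7.51, Rrm2 at 7.78 against 6.33 to 6.49 and Cenpf at 7.87 against 6.06 to 6.25. Acta1 read 8.09 in vehicle mouse 2 against 7.61 to 7.66. In prednisolone mouse 3, Lgals3 read 9.31 against 8.76 to 8.84 in the other prednisolone mice, Egr1 7.87 against 8.50 to 8.59 and Odf1 12.92 against 12.81 to 12.83. Bdh1 read 5.77 in prednisolone mouse 2 against 5.54 to 5.57, and Cemip2 6.84 in prednisolone mouse 1 against 7.11 to 7.13.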

How the results depend on the processing

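The 2 alternatives built on the epididymis score were chosen after seeing the data. The count of genes past an adjusted p of 0.05 was 0 in every limma fit run, with a lowest adjusted p of 0.12 when the epididymis score was a covariate. Taking an unadjusted p under 0.05 and a fold of at least 1.5 instead gave 127 genes, a looser rule by construction. Of 1669 recomputed values of named genes, 0 passed the threshold and 17 changed sign, among them Odf1 at -0.43 with the mean over probe sets. All deposited probe sets together, 27563 after the filter, gave 0 at the adjusted threshold and 1567 at an unadjusted p under 0.05. The 9 lists past the preset-correlation test became 0 with an estimated correlation and 0 with fry. The other settings gave 6 to 12, with a range of 6 to 10 when 1 mouse was left out. Eicosanoid, endothelial and fatty acid oxidation genes, which missed the threshold, each passed under some of these. With the epididymis score as a covariate 7 lists passed, 6 of them among the 9, and without the arrays of score over 1, 10 passed, 5 of them among the 9. Cell cycle genes reversed with array weights (median 0.11) and ranged from -0.46 to 0.28 over the fits without 1 mouse, positive without vehicle mouse 3. MHC class II genes ranged from -0.08 to 0.27 over those fits, the latter without prednisolone mouse 3. Extracellular matrix genes reversed to -0.09 without the arrays of high epididymis score. With array weights the interferon call was lost (median -0.01), and the inflammatory median was 0.35 and the macrophage median 0.61. The vehicle mice other than mouse 4 had weights of 0.58 to 0.69. The largest weights were those of prednisolone mouse 1 (2.06) and vehicle mouse 4 (2.01). Their macrophage scores were 0.42 and -0.54 and their inflammatory scores 0.45 and -0.39, so these weighted medians lean on them. The absence of vehicle mouse 3 turns the cell cycle list, and that of prednisolone mouse 3 the MHC class II list. Other causes of these changes between settings were not tested. With the replicate number as a block, 0 genes and 11 lists passed. The numbers were not taken to pair the mice, since the labels do not say that equal numbers mark a shared litter or day. Deviations of equally numbered mice correlated at -0.19, -0.58, 0.13 and -0.28, and 0 of the 4 prednisolone mice correlated best with their own number. With so few mice these correlations cannot exclude a pairing. Robust variance was not run for the lists, since camera has no such option, and the alternative with all deposited probe sets has no list test. Low signal limits Il6 and Ucp1, which lie among the dimmest genes.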

Other observations

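The tests of the epididymis transcripts and the count of genes over other splits of the mice were chosen after their results were seen, as were the fits without the mice of high epididymis score.

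Cell cycle genes were brightest in vehicle mouse 3 for 26 of 26 tested members. Mki67, a marker of dividing cells, read 10.68 there and between 7.29 and 8.37 in the other 7 mice, and Top2a read 9.26 against 5.80 to 7.12. The same mouse had the highest mesothelial score, 0.84, and its macrophage score of 0.39 was the highest of the vehicle group. MHC class II genes were lowest in prednisolone mouse 3 for 6 of 8 members, with H2-Ab1 at 10.39 there and between 11.55 and 12.16 elsewhere, and H2-Eb1 at 8.62 against 9.85 to 10.39. That mouse also had the highest value of 11 of 19 fatty acid synthesis genes, with Fasn, the fatty acid synthase, at 13.58 against 12.18 to 13.24 and Acly at 12.30 against 10.19 to 11.84. Cholesterol synthesis genes peaked in prednisolone mouse 3 or vehicle mouse 1 for 16 of 18 members, with list scores of 0.40 and 0.36, and had their lowest score in vehicle mouse 3, at -0.40.

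The epididymis genes did not share a single order of the mice. Lcn5, Rnase9 and Spint4 were brightest in vehicle mice 1 and 4, with Rnase9 at 13.24 and 12.89 and at 8.84 in prednisolone mouse 2. Lcn9, Lcn8, Cst11 and Lcn10 were brightest in prednisolone mouse 2, with Lcn9 at 13.61 there, 10.12 in vehicle mouse 1 and 5.81 in vehicle mouse 4. The spermatid genes Tnp1 and Tnp2 followed another order and read 8.78 and 8.95 in prednisolone mouse 3, where Gpx5 read 4.57. They also read 8.09 and 8.8 in vehicle mouse 1, 7.43 and 7.52 in vehicle mouse 3 and 7.02 and 7.43 in vehicle mouse 4. In the remaining mice they read at most 5.7. Members of other lists varied with the mice of high epididymis score. The desaturase Fads2 read 11.25, 10.78 and 10.80 in vehicle mice 1 and 4 and prednisolone mouse 2 and at most 9.14 elsewhere. The immediate early gene Egr2 read 9.12, 8.23 and 9.41 in them and at most 7.52 elsewhere.

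Transcripts of the epididymis reached values above 13 in 3 of 8 fat samples, from both groups, and Gpx5 read 11.27 and 8.69 in 2 more. Prednisolone as the cause is argued against by the vehicle group, which received none and whose list score spanned 4.29. Members of the list, fixed earlier, had a median correlation of 0.31, against 0.13 at the 95th percentile of 1000 random lists of like expression. Epididymal tissue in the samples is thus a candidate explanation, but the shared variation had been seen first, so this is no independent evidence for it. Of the 16 tested members, 0 belong to another list and Odf1 and Acr varied by no more than 0.36, and whether tissue came along at dissection or RNA was carried over later stays open.

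Macrophage markers averaged higher with prednisolone, by a list score difference of 0.43 ± 0.24. Chance is not excluded, with an exact permutation p of 0.143 (0.813 after adjustment over the lists), an adjusted p of 0.93 with an estimated correlation and vehicle mouse 3 inside the prednisolone range at 0.39. With the epididymis score as a covariate the difference was 0.40 ± 0.23, an error too wide to decide whether epididymal tissue may lie behind it. The epididymis score also differed by only -0.34 between the groups, against a span of 4.29 among vehicle mice. The covariate could thus hardly move the difference, and the explanations cannot be told apart. The median of 0.02 without the mice of high epididymis score decides nothing, since that fit drops the 2 vehicle mice with the lowest macrophage scores and keeps vehicle mouse 3 as 1 of 2. Prednisolone itself stays open and untested.

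The score of the immediate early genes stood higher in all 4 prednisolone mice than in any vehicle mouse, by 0.32 ± 0.06. The groups did not overlap in 5 of its 17 members, and overlapped in the rest. With the epididymis score as a covariate the difference was 0.32 ± 0.06. That score differed by -0.34 between the groups, against a span of 4.29 among vehicle mice, so the covariate could hardly move the difference. It also pools genes brightest in different mice. The pooled score therefore does not account for the difference, and epididymal tissue as such is not decided. Macrophage content, as far as the pooled macrophage score measures it, is argued against as the whole cause, at 0.31 ± 0.08 with that score as a covariate. The members of the macrophage score did not share a single order of the mice, so it does not stand for each of them. Over the 32 lists the exact permutation p of the immediate early score, 0.0286 and the smallest possible, became 0.813 after adjustment. Prednisolone and handling between death and freezing both stay open, and no value here tells them apart.

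Chance could not be excluded for the count of 9 lists past the preset-correlation test, since 22 of 35 splits of the mice into 4 and 4 gave as many, and the highest of the others gave 20. The same comparison says nothing about the count of genes: with 0 in the real split, all 35 splits had at least as many whatever they held, and the highest of the others was 0. At an unadjusted p under 0.05, 8 of the 35 splits gave as many genes as the real 842. The other splits had a median of 531.5 and a highest count of 2838, and what sets the mice apart in those splits was not tested.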
